A study of Mus musculus with 6 samples.

How the data were processed

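RNA was measured in the entire aorta of Apoe-/- mice, in 3 libraries from mice given recombinant human EPO and 3 from mice given saline. Per the labels' protocols the libraries were made with the NEBNext Ultra RNA kit, with no strand marking named, and sequenced as paired ends on a HiSeq instrument. Per the submitters' processing notes, base calls were made with CASAVA 1.8 and reads aligned with TopHat2 2.0.6 to the mouse build mm10. The counting tool, its strand setting and the annotation release are not given in the sources used here. The deposited values are counts per Ensembl gene with no normalization by the authors, which was checked on the values: all are whole numbers and the column totals differ. The table holds 47643 genes and 6 columns, all of them used, and the columns abbreviated Con were read as the Vehicle group.

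Gene symbols and GRCm38 coordinates (the same assembly as mm10) were taken from GENCODE M21 by gene ID. Of the IDs, 47224 matched and 419, which hold 0.0272% of the counts, did not; 60 symbols occur more than once. Where a gene overlaps another on the opposite strand its counts are uncertain, because the strand setting is unknown. Among the named genes this concerns Mki67, Atp2a1, Hpca, Fdft1, Irf7, Angpt2, Timp1, Tagln, Cx3cr1, Epo, Prox1, Myl2, Adm, Bmp4, Fbn2, Mybpc1 and Foxp3, among others.

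The comparison, EPO against Vehicle, was made in R 4.3.3 with edgeR 4.0.16: genes with low counts were removed with filterByExpr, libraries were scaled by TMM, and a quasi-likelihood test (glmQLFit, glmQLFTest, two-sided, group as the only term) was adjusted by the Benjamini-Hochberg method over the 16522 genes tested. The 31121 other genes were filtered out, and the tested genes hold 99.9% of the counts. A gene was called changed at an adjusted p under 0.05 with no minimum fold. The common biological coefficient of variation was 0.244 and the median log2 fold change of all tested genes 0.0113. Each adjusted p of a gene is from edgeR unless another tool is named. CPM values use the count of a library over the tested genes, scaled by its TMM factor, with means and SDs over 3 libraries. Log2 fold changes are those of the edgeR fit with its default prior count. A prior count of 2 was used for log2 CPM, from which the correlations, principal components and list medians per library came.

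The test, the gene lists and the rule for named genes were fixed before the data were examined. Lists of 567 genes in 29 groups were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested members, adjusted over 28 lists), beside it camera with an estimated correlation and fry. By the rule, the text names the 8 largest rises and the 8 largest falls among changed genes whose CPM values do not overlap between groups, leaving out gene models without a proper name and immunoglobulin and T cell receptor variable segments; Apoe, Epo and Epor; and from each list up to 3 tested members of smallest p, or up to 2 for lists of other tissues and of tissue handling. Genes named outside the rule are given as such or as members that complete a count of few genes; Acta2, Myh11, Apln, Aplnr, Vegfa, Angpt2, Pecam1 and Timp1 and the members given with their values as not passing were also chosen after their values were seen. Shares of counts were compared by an exact permutation test, two-sided, for which the smallest p is 0.1.

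A count of 0 was read as up to 3 counts, over the library for single values and over the group for folds, and ratios with 1 to 3 counts in a group have a 95% interval from counting. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules. The limit at 0 counts, taken over the unscaled total count, lay between 0.0779 and 0.129 CPM.

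The procedure was tested on simulated data with the size and spread of this comparison (seed 101, 16293 genes). It recovered 34 of 100 genes changed 2-fold and 78 of 100 changed 4-fold, and 4 of its 125 calls (3.2%) were false. In camera with the preset correlation it called the cell cycle list that had been raised (adjusted p = 5.94e-44) and 0 of 27 other lists. Genes were drawn independently of each other, so this does not show how often lists of correlated genes would be called falsely. With 125 calls against 3804 in the real comparison, the simulation's threshold was stricter on the unadjusted p. Its recovery therefore does not carry over in size, and genes that changed 2-fold may still have been missed.

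Alternatives tried were other scalings (size factors of DESeq2, library size alone), no filter and a filter of at least 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom with and without sample weights, robust dispersion, the replicate number as a block, removal of haemoglobin and mitochondrial genes, an adjusted p under 0.1, a fold of at least 2, and each library left out. Chosen after seeing the data were libraries thinned to the smallest total, a fit without EPO 1 and EPO 2, and removal of the genes of the skeletal muscle, chondrocyte-like and adipocyte lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample was left out.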

Results

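RNA sequencing was used to compare the aortas of Apoe-/- mice given erythropoietin with those of Apoe-/- mice given saline. Apoe-/- mice lack apolipoprotein E, a lipid-carrying protein of the blood, and develop raised plasma cholesterol and atherosclerosis. Erythropoietin (EPO) is the hormone that drives red cell production. The EPO group received the recombinant human hormone by intraperitoneal injection at 5000 IU per kg per day, and the Vehicle group received saline by the same route, each for 4 weeks. The entire aorta was taken, and each group had 3 libraries. The labels do not say in so many words that every library came from a different animal, so the p-values measure the spread between these 6 libraries. The total count was 23278649, 25855856 and 27904322 in Vehicle 1, Vehicle 2 and Vehicle 3, and 38502430, 28798632 and 32553720 in EPO 1, EPO 2 and EPO 3. A gene with 0 counts in a library could lie at up to 0.0779 CPM in EPO 1, the deepest, and up to 0.129 CPM in Vehicle 1, the shallowest, from counting error alone. The title of the series links EPO to abdominal aortic aneurysm through new vessel formation and infiltration by inflammatory cells, and the design implies 1 comparison, EPO against Vehicle.

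Apoe itself, the gene targeted in both groups (ENSMUSG00000002985, GRCm38 chromosome 7, 19696109 to 19699188), had 176, 516 and 494 counts in Vehicle 1, 2 and 3 and 1385, 335 and 463 counts in EPO 1, 2 and 3. Its level was 14.9 ± 6.47 CPM in Vehicle and 21.3 ± 15.1 CPM in EPO (SD, n = 3 each), a difference within the spread between libraries (log2 fold change 0.51, SE 0.52, edgeR adjusted p = 0.512). Wild-type aorta was not analysed here, so these counts do not test the knockout. Epor, the EPO receptor (ENSMUSG00000006235, chromosome 9, 21958897 to 21963506), was at 2.67 ± 0.544 CPM in Vehicle and 3.99 ± 2.17 CPM in EPO (log2 fold change 0.58, SE 0.41, edgeR adjusted p = 0.346), with 6.39 CPM in EPO 1 against 2.14 and 3.46 CPM in EPO 2 and EPO 3. Epo, the mouse hormone gene (ENSMUSG00000029711, chromosome 5, 137483020 to 137533242), had 3 counts in Vehicle 3, 1 count in EPO 3 and 0 in the other libraries, too few to be tested.

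With EPO, 14 of 26 collagen and elastic fibre genes and 19 of 21 cell cycle genes were higher and none lower, and of 26 matrix proteases and their inhibitors 12 were higher and 2 lower. Of 20 contractile smooth muscle genes 17 were lower. With an estimated correlation the list test kept its call for collagen and elastic fibre (adjusted p = 0.023) and lost it for the other lists (0.221 each). Col1a1, a chain of type I collagen, was 7.47-fold higher (3440 ± 553 CPM in Vehicle and 25700 ± 3370 CPM in EPO), and Mmp14, a membrane-bound matrix protease, was 5.89-fold higher (194 ± 23.1 and 1140 ± 138 CPM). Mki67, a marker of dividing cells, rose 5.92-fold, from 8.92 ± 2.33 to 52.8 ± 6.74 CPM. Acta2, smooth muscle actin, was 3.08-fold lower (10400 ± 2060 and 3380 ± 638 CPM). Markers of skeletal muscle and of fat moved with the groups as well: genes of the skeletal muscle list took 0.00613% ± 0.00148 of the counts in Vehicle and 0.174% ± 0.153 in EPO (SD, n = 3), and 10 of 15 white adipocyte genes were lower.

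Of 16522 genes tested, 3804 (23%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 2133 of them higher with EPO and 1671 lower. A change of at least 2-fold was seen in 1329 higher and 919 lower genes, and of at least 8-fold in 167 higher and 14 lower genes. The CPM values of 7243 genes (43.8%) did not overlap between the groups, where chance gives 10%. Across genes, the correlation of log2 CPM between libraries ran from 0.963 to 0.983 within groups and from 0.914 to 0.95 between groups. The first principal component (62.2% of the variance) separated EPO from Vehicle, and the second (16%) set EPO 1 apart from EPO 2 and EPO 3. The number of changed genes was 1635 (936 higher, 699 lower) without Vehicle 1 and 2029 (1075 higher, 954 lower) without Vehicle 2, the number of higher genes was 1379 without Vehicle 3, and the number of lower genes was 941 without EPO 2. In a fit chosen after seeing the data, which left out EPO 1 and EPO 2, the libraries with most skeletal muscle counts, 1548 genes changed (1085 higher, 463 lower).

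**Figure D1:**
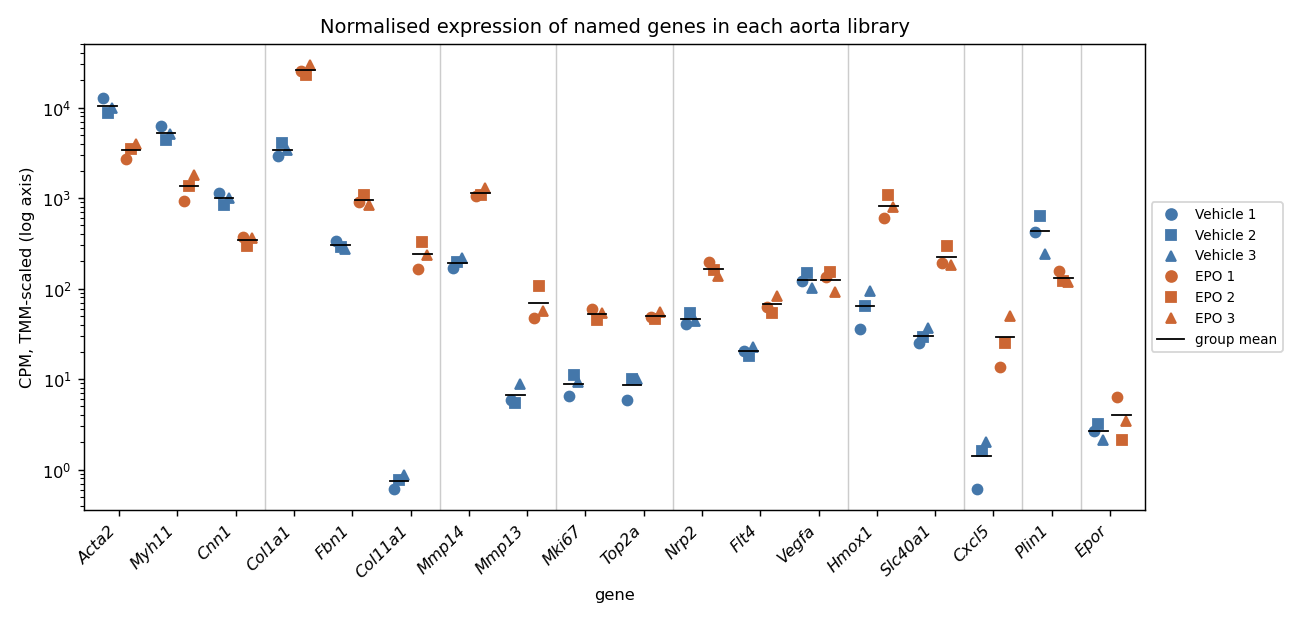
CPM of 18 named genes (horizontal axis) in each of the 6 libraries, on a log axis, with Vehicle in blue, EPO in orange and black bars at the group means. The 3 EPO libraries lie below the 3 Vehicle libraries for Acta2, Myh11, Cnn1 and Plin1 and above them for Col1a1, Mmp14 and Mki67, while Vegfa and Epor overlap.

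The 8 largest rises by fitted log2 fold change among genes whose groups did not overlap were those (gene models without a proper name left out) of Mybpc1, Myh2, Brinp3, Slc5a7, Fbn2, Myot, Myl2 and Col11a1. Col11a1, a chain of the cartilage collagen type XI (ENSMUSG00000027966, chromosome 3, 114030540 to 114220718), went from 0.75 ± 0.129 CPM in Vehicle to 243 ± 82 CPM in EPO (SD, n = 3; log2 fold change 8.32, SE 0.35, adjusted p = 0.000416). Fbn2, a microfibril protein (ENSMUSG00000024598, chromosome 18, 58008623 to 58210487), had 5 counts over the Vehicle group and reached 14.6, 25.9 and 50.1 CPM in EPO 1, 2 and 3 (adjusted p = 0.00146). Slc5a7, the choline transporter of cholinergic neurons (ENSMUSG00000023945, chromosome 17, 54273590 to 54299034), had 0 counts in Vehicle and 312 in EPO and was at least 82-fold higher, taking 3 counts over the Vehicle group as the limit (adjusted p = 0.00407). That limit lies below the fitted 227-fold of Acta1, which is not among the 8, so the place of Slc5a7 rests on the fitted fold. The places of Brinp3, Fbn2, Myot and Myl2, with 1 to 5 Vehicle counts each, are uncertain too, since their 95% counting intervals start between 149 and 199. Brinp3 (ENSMUSG00000035131, chromosome 1, 146494760 to 146902472) had 1 count in Vehicle and 1257 in EPO, a ratio of 991 (95% counting interval 178 to 39200; adjusted p = 0.000836). The other 4 encode striated muscle proteins and differed widely between EPO libraries. Mybpc1, the slow form of myosin-binding protein C (ENSMUSG00000020061, chromosome 10, 88518279 to 88605152), had 3 counts in Vehicle and 6175 in EPO, a ratio of 1620 (95% counting interval 555 to 7870), with 35.7, 151 and 13.9 CPM in EPO 1, 2 and 3. Myh2, a fast myosin heavy chain (ENSMUSG00000033196, chromosome 11, 67171027 to 67197517), stood at 140, 480 and 15.5 CPM, and the Z-disc gene Myot (ENSMUSG00000024471, chromosome 18, 44334074 to 44355724) at 14.4, 51.5 and 6.07 CPM. Myl2, a myosin light chain of slow skeletal and ventricular muscle (ENSMUSG00000013936, chromosome 5, 122100951 to 122113472), stood at 9.59, 62.7 and 0.661 CPM. With limma-voom, Myh2 (adjusted p = 0.0808) and Myl2 (adjusted p = 0.179) missed the threshold, and Myl2 also missed it without Vehicle 1, Vehicle 2 or Vehicle 3 (adjusted p = 0.0816, 0.0775 and 0.0613 in edgeR).

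By the same rule the 8 largest falls were those of Slc26a4, Awat1, Sv2c, H2-M2, Hpca, Hhip, Cpne6 and Dner, all of them low in Vehicle. H2-M2, a class Ib histocompatibility gene (ENSMUSG00000016283, chromosome 17, 37480851 to 37483552), went from 7.78 ± 2.49 to 0.646 ± 0.0688 CPM (SD, n = 3; log2 fold change -3.58, SE 0.33, adjusted p = 0.00167), and Hhip, a secreted antagonist of Hedgehog ligands (ENSMUSG00000064325, chromosome 8, 79965851 to 80058006), from 7.87 ± 3.71 to 0.785 ± 0.467 CPM (adjusted p = 0.00643). Slc26a4, the anion exchanger pendrin (ENSMUSG00000020651, chromosome 12, 31519827 to 31559969), had 58 counts in Vehicle and 0 in EPO and was at least 24.5-fold lower, taking 3 counts over the EPO group as the limit. Awat1 (ENSMUSG00000015665, chromosome X, 100572251 to 100578205), an enzyme of wax ester synthesis, had 68 counts in Vehicle and 4 in EPO, and Cpne6 (ENSMUSG00000022212, chromosome 14, 55510445 to 55517431) had 132 and 17. Sv2c, Hpca and Dner, which are best known from neurons, had most of their Vehicle counts in Vehicle 3, with 196 of 230, 169 of 226 and 180 of 292. Sv2c (ENSMUSG00000051111, chromosome 13, 95954594 to 96132577) lost its call without Vehicle 1, Vehicle 3, EPO 1, EPO 2 or EPO 3 (edgeR adjusted p from 0.0596 to 0.106), Hpca (ENSMUSG00000028785, chromosome 4, 129111570 to 129122036) without EPO 1 (0.0574) or EPO 2 (0.0629), and Dner (ENSMUSG00000036766, chromosome 1, 84369839 to 84696221) without EPO 2 (0.0548).

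Gene lists fixed in advance were used to describe groups of genes. Of 28 lists with enough tested members, 21 shifted as a whole in camera with a preset correlation, 14 upward and 7 downward. With an estimated correlation between genes the call held for 1 list, collagen and elastic fibre, whose estimate was -0.0315. By fry, which asks whether the genes of a list move on balance one way, 9 lists passed: collagen and elastic fibre, contractile smooth muscle cell, cell cycle, matrix proteases, angiogenic factors, iron and haem handling, chondrocyte-like, skeletal muscle fibre and circadian clock. Each list below is given with its members past the threshold over all genes tested, the count adjusted over the list alone, and its camera adjusted p with either correlation.

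**Figure D2:**
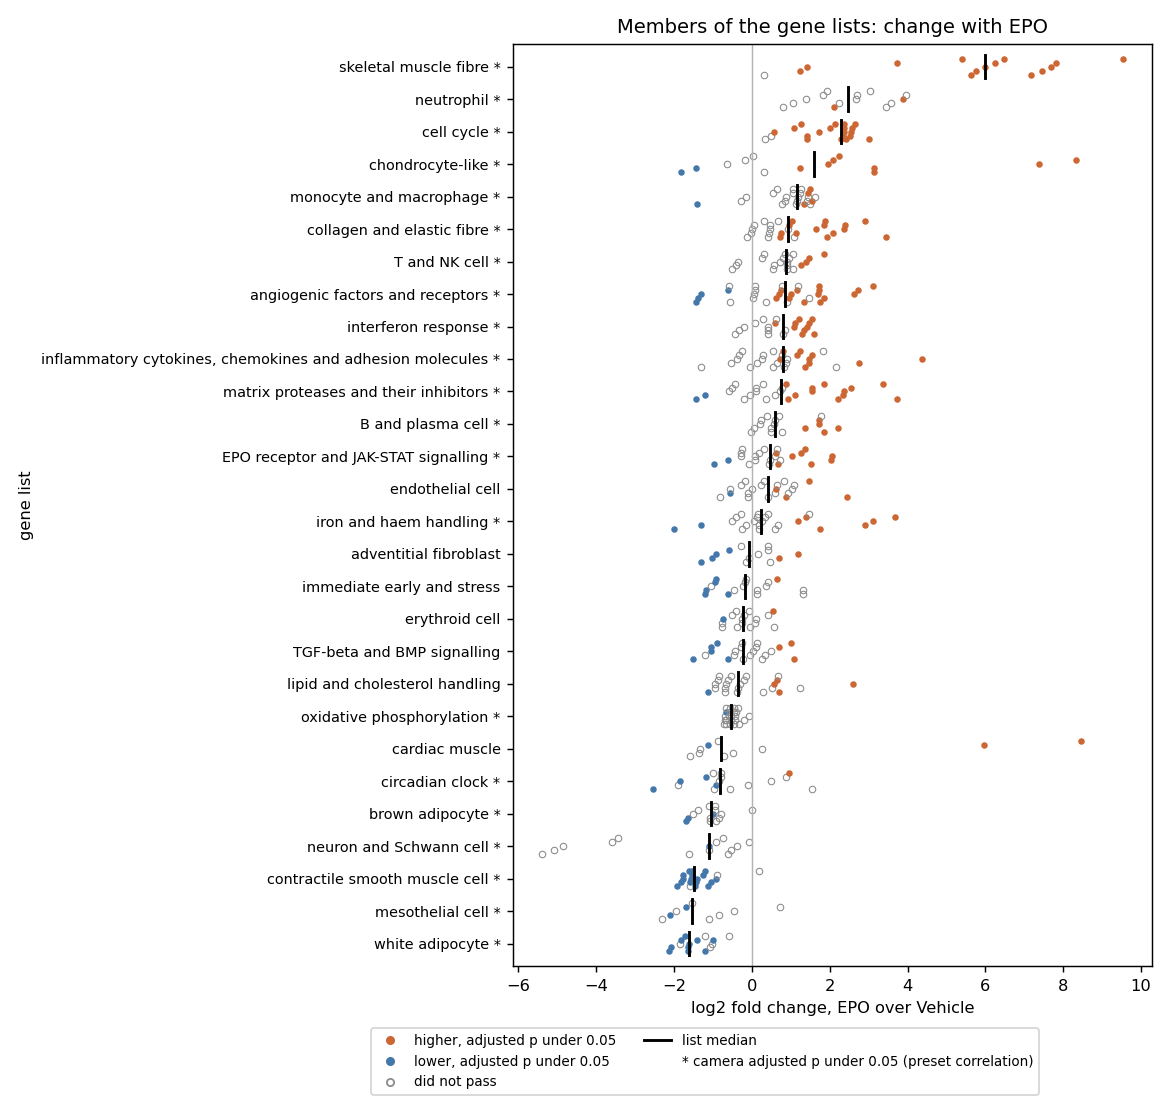
Log2 fold change (EPO over Vehicle, horizontal axis) of every tested member of the 28 gene lists (vertical axis, sorted by median), filled where the gene passed an adjusted p under 0.05, with black bars at list medians and a star where camera with a preset correlation passed. The medians run from -1.62 for white adipocyte to 5.98 for skeletal muscle fibre.

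Contractile smooth muscle genes fell. Of 20 tested, 17 were lower and 0 higher (adjusted over the list alone, 19 lower and 0 higher), with a median log2 fold change of -1.49. Myocd, the coactivator that switches on contractile genes, fell 2.66-fold from 20.2 ± 2.94 to 7.59 ± 0.31 CPM, Cnn1 fell 2.89-fold and Rgs5, a signalling regulator of smooth muscle and pericytes, 3.51-fold (edgeR adjusted p = 0.00262, 0.00277 and 0.00331). Myh11, smooth muscle myosin, was at 5240 ± 921 and 1370 ± 449 CPM. The members that did not pass were Pln, Cald1 and Des, with log2 fold changes of -1.6, -0.91 and 0.19. For the list, camera gave an adjusted p of 3.54e-15, and 0.221 with an estimated correlation. Without Vehicle 1 the count of lower members was 9, and without both EPO 1 and EPO 2 it was 10. In the same libraries the list of white adipocyte genes also fell, with a median of -1.62, and skeletal muscle genes rose (adjusted p = 0.384 and 0.221 with an estimated correlation, so neither list kept its call).

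Collagen and elastic fibre genes rose. Of 26 tested, 14 were higher and 0 lower (adjusted over the list alone, 19 and 0), with a median log2 fold change of 0.94. Col5a1 rose 3.68-fold (543 ± 17.6 to 2000 ± 211 CPM), Col1a1 7.47-fold and Fbn1, the main microfibril protein, 3.13-fold (302 ± 34.7 to 945 ± 119 CPM), at edgeR adjusted p = 0.0014, 0.00167 and 0.00218. Col1a1, Col1a2 and Col3a1 together took 1.1% ± 0.153 of all counts in Vehicle and 6.03% ± 1.23 in EPO (SD, n = 3), with every EPO library above every Vehicle library (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). Eln, the gene of elastin, had a log2 fold change of 1.09 and did not pass (adjusted p = 0.0736). By camera the list had an adjusted p of 3.92e-15, and 0.023 with an estimated correlation. Skeletal muscle counts were 0.131%, 0.343% and 0.0471% of the total in EPO 1, 2 and 3, while the list medians relative to Vehicle were 1.11, 0.99 and 0.68.

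Of 26 matrix proteases and their inhibitors, 12 were higher and 2 lower (adjusted over the list alone, 12 and 2), with a median log2 fold change of 0.74. The median above Vehicle was 0.97, 0.48 and 0.28 in EPO 1, 2 and 3, and the median log2 fold change was 0.30 without EPO 1, 0.26 without EPO 1 and EPO 2 and 0.37 in limma-voom with sample weights. The macrophage list moved with it: in both the libraries ran upward in the order Vehicle 1, 2 and 3, EPO 3, EPO 2 and EPO 1, with macrophage medians of 0.59, 0.68 and 1.70 in the last 3. Mmp14 rose 5.89-fold, the collagenase Mmp13 10.4-fold (6.7 ± 1.79 to 69.9 ± 31.9 CPM) and the gelatinase Mmp2 5.05-fold (254 ± 45.6 to 1280 ± 342 CPM), at edgeR adjusted p = 0.000836, 0.00231 and 0.00231. The inhibitor Timp1 was among the higher genes (log2 fold change 1.86), though without Vehicle 2 its adjusted p was 0.0814. The lower members, named after their values were seen, were Timp4 (-1.44) and Adamts1 (-1.21). Without Vehicle 2, Vehicle 3 or EPO 3 Adamts1 missed the threshold (adjusted p = 0.0648, 0.0558 and 0.0529), leaving 1 lower member. This list had a camera adjusted p of 5.32e-06, and 0.221 with an estimated correlation.

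Cell cycle genes rose almost as a whole. Of 21 tested, 19 were higher and 0 lower (adjusted over the list alone, 21 and 0), with a median log2 fold change of 2.29. Besides Mki67, Top2a, the topoisomerase of dividing cells, rose 5.78-fold (8.64 ± 2.44 to 50 ± 4.8 CPM) and Mcm5, a subunit of the replicative helicase, 3.30-fold (9.37 ± 1.52 to 31 ± 5.5 CPM), at edgeR adjusted p = 0.0012, 0.00149 and 0.00258. Mcm6 and Mcm4 did not pass, with log2 fold changes of 0.35 and 0.50. In camera the adjusted p was 1.93e-22, and 0.221 with an estimated correlation. The count of higher members stayed between 17 and 19 with single libraries left out and was 19 without EPO 1 and EPO 2. The median over the list was 1.91, 2.10 and 2.60 above Vehicle in EPO 1, 2 and 3, the libraries with 0.131%, 0.343% and 0.0471% of skeletal muscle counts.

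Among 30 angiogenic factors and receptors, 15 were higher and 4 lower (adjusted over the list alone, 18 and 6), with a median log2 fold change of 0.84. Nrp2, a coreceptor for VEGF-C and semaphorins, rose 3.62-fold (45.9 ± 6.79 to 166 ± 30 CPM), Flt4, the receptor of VEGF-C, 3.28-fold (20.4 ± 2.3 to 66.8 ± 15.1 CPM) and Pgf, placental growth factor, 3.25-fold (7.35 ± 0.947 to 23.9 ± 5.28 CPM), at edgeR adjusted p = 0.00188, 0.00251 and 0.00289. Apln and its receptor Aplnr rose as well (log2 fold changes 2.63 and 3.10). So did Thbs1, an inhibitor of vessel growth (2.72, edgeR adjusted p = 0.0119), named after its value was seen and not followed over the settings. The list thus holds genes of opposed roles, so its rise alone does not say whether vessel growth was promoted. Vegfa and Angpt2 did not pass (log2 fold change 0.03, SE 0.22, adjusted p = 0.94, and 0.07, SE 0.28, adjusted p = 0.88). The lower members, named after their values were seen, were Adm (-1.38), Vegfd (-1.31), Fgf1 (-1.45) and Epas1 (-0.60); Fgf1 and Epas1 lost their calls without Vehicle 1, Vehicle 2, Vehicle 3 or EPO 2, and Epas1 also without EPO 3 (adjusted p from 0.0606 to 0.119). The camera adjusted p was 0.00023, and 0.221 with an estimated correlation. Without Vehicle 1 the higher members numbered 7, without EPO 1 and EPO 2 they numbered 9, and the lower members numbered 2 without Vehicle 1, Vehicle 2, Vehicle 3 or EPO 2.

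Endothelial cell genes did not shift as a list (median log2 fold change 0.40, camera adjusted p = 0.0979, and 0.565 with an estimated correlation). Of 21 tested, 4 were higher and 1 lower (adjusted over the list alone, 4 and 1). Prox1, a transcription factor of lymphatic endothelium, rose 5.49-fold (1.57 ± 0.0879 to 8.64 ± 2.7 CPM), Robo4 2.78-fold and Cdh5, endothelial cadherin, 1.83-fold (edgeR adjusted p = 0.00263, 0.00687 and 0.0117). Fli1 was the other higher member (log2 fold change 0.63), and Pecam1, an adhesion molecule of all endothelium, the lower one (542 ± 20.2 to 364 ± 34.3 CPM, log2 fold change -0.57); both were named after their values were seen. Without Vehicle 1, Cdh5 (adjusted p = 0.0545) and Fli1 (0.106) missed the threshold, which left 2 higher members, and Fli1 also missed it without Vehicle 3, EPO 2 or EPO 3 (from 0.0682 to 0.0779). Without Vehicle 1, Vehicle 2, Vehicle 3, EPO 2 or EPO 3, Pecam1 missed it (adjusted p from 0.0604 to 0.0827). The list passed camera with a preset correlation without EPO 2 (adjusted p = 0.0416) or EPO 3 (0.0223), and with no filter on low counts (0.0211). The median relative to Vehicle was 0.755, 0.244 and -0.00694 in EPO 1, 2 and 3. The median log2 fold change was 0.06 without EPO 1, with 5 higher and 3 lower members, and -0.04 without EPO 1 and EPO 2, with 1 higher and 2 lower. It was 0.145 in limma-voom with sample weights, with 3 lower members. DESeq2 called 8 higher and 3 lower, and without a filter on low counts 7 were higher and 1 lower.

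Of 28 inflammatory cytokines, chemokines and adhesion molecules tested, 10 were higher and 0 lower (adjusted over the list alone, 11 and 0), with a median log2 fold change of 0.79. Cxcl5, a neutrophil-attracting chemokine, rose 20.7-fold (1.4 ± 0.716 to 29.5 ± 18.8 CPM), Nlrp3, the inflammasome sensor, 2.75-fold (3.49 ± 0.959 to 9.65 ± 1.19 CPM) and Cxcl2 6.68-fold (1.51 ± 0.462 to 10.2 ± 6.87 CPM), at edgeR adjusted p = 0.00375, 0.00763 and 0.0111 (Cxcl2 0.0539 without Vehicle 1). The adhesion molecules Vcam1, Icam1, Sele and Selp did not pass, with log2 fold changes of 0.12, -0.26, -0.34 and -0.38. The camera adjusted p was 0.00097, and 0.526 with an estimated correlation. The higher members numbered 2 without Vehicle 1, 3 without Vehicle 2, 6 without EPO 2, 4 without EPO 3 and 4 without EPO 1 and EPO 2.

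The lists of immune cell markers shifted upward with a preset correlation, and the number of single genes that passed depended on the tool and the filter. Of 23 monocyte and macrophage genes, 4 were higher and 1 lower (adjusted over the list alone, 12 and 1; median log2 fold change 1.17; camera adjusted p = 0.000286, and 0.526 with an estimated correlation). The fractalkine receptor Cx3cr1 rose 2.79-fold (16.7 ± 4.45 to 46.7 ± 5.36 CPM), the Fc receptor Fcgr1 2.72-fold and the macrophage marker Adgre1 2.93-fold (edgeR adjusted p = 0.00453, 0.00689 and 0.0161; Adgre1 0.0587 without Vehicle 1). The others, named after their values were seen, were the scavenger receptor Msr1 (log2 fold change 1.33) and the lower gene Lyz1 (-1.42). Its close relative Lyz2, at 1706 CPM in Vehicle and 2927 CPM in EPO, had a log2 fold change of 0.78 and did not pass (edgeR adjusted p = 0.169). If these genes share reads, the counts of Lyz1 are uncertain. DESeq2 called 14 higher members, as did edgeR with no filter on low counts. The median above Vehicle was 1.70, 0.68 and 0.59 in EPO 1, 2 and 3, and the median log2 fold change was 0.55 without EPO 1, 0.54 without EPO 1 and EPO 2 and 0.70 in limma-voom with sample weights. Without EPO 2 there were 7 higher members, without EPO 1 and EPO 2 there was 1, Msr1 lost its call without Vehicle 2 (adjusted p = 0.0584), and Lyz1 without Vehicle 2, Vehicle 3, EPO 2 or EPO 3 (adjusted p from 0.0684 to 0.13). All 14 tested neutrophil genes had a fold change above 0 (median log2 fold change 2.46), but 2 passed, Mpo (0.0994 ± 0.0677 to 1.55 ± 0.818 CPM, adjusted p = 0.00624) and the G-CSF receptor Csf3r (13.6 ± 5.8 to 58.8 ± 48.9 CPM, adjusted p = 0.0376); adjusted over the list alone 1 was higher and 0 lower. Csf3r lost its call without Vehicle 1, Vehicle 2, Vehicle 3 or EPO 3 (adjusted p from 0.0501 to 0.136). The third by p, Ngp, had a log2 fold change of 3.96 and an adjusted p of 0.0577 (0.0273 without EPO 1). The neutrophil list had a camera adjusted p of 0.00306, and 0.526 with an estimated correlation; its median above Vehicle was 0.84, 1.67 and 3.77 in EPO 1, 2 and 3, and 9 members passed without EPO 1, 12 without EPO 1 and EPO 2, and 1 without Vehicle 1, Vehicle 2 or EPO 3. Without EPO 3 the median log2 fold change was 1.13. The higher neutrophil genes numbered 6 in DESeq2, 10 with no filter on low counts, 9 with the replicate block and 1 with limma-voom.

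Of 20 T and NK cell genes, 4 were higher and 0 lower (adjusted over the list alone, 3 and 0; median log2 fold change 0.87; camera adjusted p = 0.00701, and 0.526 with an estimated correlation). Thy1, which stromal cells also make, rose 3.62-fold (53.6 ± 11.3 to 194 ± 27.6 CPM, edgeR adjusted p = 0.00228), and the higher genes also included Cd5 (1.26 ± 0.214 to 3.03 ± 0.911 CPM, 0.0301) and Foxp3, the transcription factor of regulatory T cells (0.206 ± 0.0572 to 0.572 ± 0.108 CPM, 0.0366). The count was 1 without Vehicle 1, Vehicle 2, EPO 1 or EPO 3, and without EPO 1 the list's camera adjusted p was 0.0581. The median was 0.58 without Vehicle 1 and 1.36 without Vehicle 3. Foxp3 missed the threshold whichever library was left out (adjusted p from 0.0715 to 0.144), and in DESeq2 (0.0882), and Cd5 without any library other than EPO 2 (from 0.0559 to 0.11). Of 17 B and plasma cell genes, 5 were higher and 0 lower (adjusted over the list alone, 5 and 0; median log2 fold change 0.58; camera adjusted p = 0.0302, and 0.526 with an estimated correlation). They were the immunoglobulin chain genes Ighm (49.4 ± 11.1 to 162 ± 87.1 CPM), Igkc (39.3 ± 20 to 182 ± 123 CPM) and Iglc2, and Jchain (10.6 ± 2.64 to 38.1 ± 24.2 CPM) and Mzb1, which antibody-secreting cells make. Their adjusted p lay between 0.0264 and 0.0463, and Iglc2 and Mzb1 were named after their values were seen. Ms4a1, a surface protein of B cells, had a log2 fold change of 0.40 and did not pass. The count was 0 without Vehicle 1, Vehicle 2 or EPO 1, 1 without Vehicle 3, 2 without EPO 3 and 2 with limma-voom, the 5 genes' adjusted p where leaving out 1 library ended a call lay between 0.0556 and 0.139, and the list's camera adjusted p was 0.0585 without Vehicle 3, 0.0962 without EPO 1 and 0.185 without EPO 3. The median of that list was 0.88 without EPO 2 and 1.07 without EPO 1 and EPO 2, and 1 member passed with the replicate block.

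Of 21 interferon response genes, 10 were higher and 0 lower (adjusted over the list alone, 13 and 0), with a median log2 fold change of 0.80. Ifi44 rose 2.79-fold (4.69 ± 0.419 to 13.1 ± 3.26 CPM), Irf7, a transcription factor of the interferon response, 2.45-fold and the antiviral GTPase Mx1 2.91-fold (edgeR adjusted p = 0.00532, 0.00607 and 0.00774). The camera adjusted p was 0.000101, and 0.526 with an estimated correlation, and the higher members numbered 5 without Vehicle 1 or Vehicle 2. The median was 0.53 without EPO 3 and 1.27 without EPO 1 and EPO 2. Neutrophil markers moved with the list: both ran upward in the order Vehicle 1, 2 and 3 and, among the EPO libraries, EPO 1, 2 and 3, with medians above Vehicle of 0.44, 0.65 and 1.28 for interferon response and 0.84, 1.67 and 3.77 for neutrophil. Of 23 genes of EPO receptor and JAK-STAT signalling, 8 were higher and 2 lower (adjusted over the list alone, 9 and 2), with a median of 0.45. The Src-family kinase Lyn rose 2.41-fold (34 ± 7.98 to 81.8 ± 5.18 CPM), Myc 2.03-fold and Socs3, a feedback inhibitor of cytokine signalling, 4.11-fold (32.3 ± 12 to 133 ± 57.3 CPM), at adjusted p = 0.00457, 0.00706 and 0.00945. The lower members, named after their values were seen, were Socs2 (-0.61) and the leptin receptor Lepr (-0.97). Cish, a STAT5 target, had a log2 fold change of 0.45 and did not pass. The camera adjusted p was 0.0302, 0.435 with an estimated correlation, 0.0962 without EPO 1, where the median was 0.29, 0.0541 without EPO 1 and EPO 2, and 0.08 in limma-voom with sample weights. The median above Vehicle was 0.41, 0.21 and 0.38 in EPO 1, 2 and 3; that of the macrophage list, also highest in EPO 1, was 1.70, 0.68 and 0.59. The higher members numbered 3 without Vehicle 1 and 4 without Vehicle 2, and without Vehicle 1 Lepr missed the threshold (adjusted p = 0.0536), leaving 1 lower member.

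Erythroid genes did not shift as a list (median log2 fold change -0.23, camera adjusted p = 0.452, and 0.774 with an estimated correlation). The median was -0.41 without Vehicle 1, -0.05 without Vehicle 2 and 0.04 without EPO 1 or without EPO 1 and EPO 2. Of 16 tested, 1 was higher and 1 lower (adjusted over the list alone, 1 and 1). Bpgm, the red cell enzyme that makes 2,3-bisphosphoglycerate, fell from 51.6 ± 5.24 to 30.6 ± 1.3 CPM (edgeR adjusted p = 0.00603), and Slc25a37, a mitochondrial iron importer, was at 29.4 ± 0.96 and 42.6 ± 6.55 CPM (0.0325). Slc25a37 missed the threshold without Vehicle 1, Vehicle 2, Vehicle 3, EPO 2 or EPO 3 (adjusted p from 0.0809 to 0.138) and with library sizes alone as scaling (0.0608). Fech, the next by p, had a log2 fold change of -0.26 and did not pass. Haemoglobin genes took 0.123% ± 0.0428 of counts in Vehicle and 0.105% ± 0.0533 in EPO (exact permutation p = 0.6). Their copies share near-identical sequence, so single haemoglobin genes are uncertain. Of 24 genes of iron and haem handling, 6 were higher and 2 lower (adjusted over the list alone, 9 and 2), with a median log2 fold change of 0.22. Slc40a1, the iron exporter ferroportin, rose 7.47-fold (30.1 ± 5.83 to 225 ± 63.5 CPM), Tfr2, the second transferrin receptor, 8.69-fold (1.49 ± 0.511 to 13 ± 0.532 CPM) and Hmox1, which breaks down haem, 12.8-fold (64.4 ± 28.7 to 825 ± 232 CPM), at adjusted p = 0.00119, 0.00134 and 0.00238. The lower members, named after their values were seen, were Bmp6 (95.6 ± 19.5 to 23.8 ± 16.6 CPM) and the haemoglobin scavenger receptor Cd163 (log2 fold change -1.31). The list's camera adjusted p was 0.00699, and 0.387 with an estimated correlation and 0.0638 in limma-voom with sample weights, where the call was lost, and its median was 0.12 without Vehicle 1. The lower members numbered 1 without Vehicle 1, Vehicle 2 or EPO 2 and 0 without Vehicle 3, with adjusted p for Bmp6 of 0.0508 without Vehicle 3 and 0.0559 without EPO 2, and for Cd163 from 0.0799 to 0.126 without Vehicle 1, Vehicle 2, Vehicle 3 or EPO 2.

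In 3 further lists members went both ways or few passed. Of 21 TGF-beta and BMP signalling genes, 3 were higher, Smad3 (31.7 ± 2.41 to 63.4 ± 6.09 CPM), Tgif1 (17 ± 3.09 to 35.9 ± 1.05 CPM) and Tgfbr2, and 5 lower, Bmp4 (68.9 ± 17.1 to 24.2 ± 7.36 CPM), Ltbp1, Id2, Tgfbr3 and Smad6 (adjusted over the list alone, 3 and 6; median log2 fold change -0.24; camera adjusted p = 0.355, and 0.526 with an estimated correlation). The median was -0.08 without Vehicle 3, -0.15 without EPO 1, EPO 3 or both EPO 1 and EPO 2, and -0.12 in limma-voom with sample weights. There were 5 higher members without EPO 1 and 3 lower ones without Vehicle 1, where Tgfbr3 (adjusted p = 0.0552) and Smad6 (0.126) lost their calls. Smad6 also lost its call without Vehicle 2, Vehicle 3, EPO 2 or EPO 3 (from 0.0528 to 0.113), and Tgfbr2 without Vehicle 1 (0.0814) or Vehicle 3 (0.0633). Of 23 lipid and cholesterol handling genes, 4 were higher and 1 lower (adjusted over the list alone, 4 and 3; median -0.36, mean -0.09; camera adjusted p = 0.568, and 0.758 with an estimated correlation). Fdft1, squalene synthase, fell from 41.2 ± 3.3 to 18.7 ± 3.06 CPM (edgeR adjusted p = 0.00355). The oxidised LDL receptor Olr1 rose from 1.94 ± 1.01 to 11.8 ± 7.05 CPM (0.0158), with the cholesterol esterifying enzyme Soat1 (0.0148), Scarb1 and Lipa as the other higher members. The higher members numbered 1 without Vehicle 1 or Vehicle 2 and 2 without Vehicle 3, and the lower ones 2 without Vehicle 3 and 4 without EPO 1 or in DESeq2. Lost calls were those of Soat1 without Vehicle 1 (adjusted p = 0.0697) or Vehicle 2 (0.063), Olr1 without Vehicle 2 (0.0528), Scarb1 without Vehicle 1 (0.0736) or Vehicle 3 (0.0613), and Lipa without any library other than EPO 1 (from 0.0532 to 0.136). All 23 tested genes of oxidative phosphorylation had a fold change below 0 (median log2 fold change -0.53; camera adjusted p = 0.00097, and 0.533 with an estimated correlation), but 1 passed, Ndufa9 (96.5 ± 24.9 to 60.3 ± 4.58 CPM, adjusted p = 0.047), and 0 when adjusted over the list alone. Brown adipocyte markers moved with them: in both lists the libraries ran downward in the order Vehicle 2, Vehicle 1, EPO 1, EPO 2, Vehicle 3 and EPO 3. The medians relative to Vehicle were 0.285, 0.151, -0.25, -0.468, -0.471 and -0.782 for oxidative phosphorylation and 0.693, 0.322, -0.775, -0.824, -0.979 and -1.45 for brown adipocyte, so Vehicle 3 lay among the EPO libraries in both. Without EPO 1 and EPO 2 the median log2 fold change was -0.82. By the other tools DESeq2 called 7 and limma-voom 0. The count was 10 without Vehicle 3, 2 without EPO 1, and 0 without any 1 of the other libraries. Ndufa9 lost its call without any library other than Vehicle 3 (adjusted p from 0.069 to 0.138). Sdha and Ndufs1 had log2 fold changes of -0.71 and -0.67 and adjusted p of 0.0577 and 0.0756 (0.0186 and 0.0219 without Vehicle 3). Transcripts of the mitochondrial genome took 5.85% ± 1.2 of counts in Vehicle and 3.49% ± 0.559 in EPO, with the groups apart (exact permutation p = 0.1). Of the genes in this paragraph Tgfbr2, Ltbp1, Id2, Tgfbr3, Smad6, Scarb1 and Lipa were named after their values were seen.

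Markers of other tissues and cell types were listed as well, among them adventitial fibroblasts, which belong to the aortic wall. Of 15 skeletal muscle fibre genes tested, 14 were higher and 0 lower (adjusted over the list alone, 14 and 0; median log2 fold change 5.98; camera adjusted p = 6.1e-16, and 0.221 with an estimated correlation). Pvalb, a calcium buffer of fast fibres, was at 0.115 ± 0.0328 and 24.6 ± 11.7 CPM, and Atp2a1, the calcium pump of fast fibres, at 1.13 ± 0.448 and 165 ± 144 CPM (edgeR adjusted p = 0.00105 and 0.0024). Casq1 did not pass (log2 fold change 0.31). The list took between 0.00519% and 0.00784% of counts in the Vehicle libraries. Myosin heavy chain genes share sequence, so the counts of single ones are uncertain. Of 10 cardiac muscle genes tested, 2 were higher, Myl2 and Myh7, which slow skeletal fibres also make, and 1 lower, Ryr2, named after its values were seen (adjusted over the list alone, 2 and 1). The median log2 fold change of that list was -0.79 (0.08 without Vehicle 1, -1.19 without EPO 2, -0.51 without EPO 3 and -1.41 without EPO 1 and EPO 2), the mean 0.72, and the camera test pointed down (adjusted p = 0.669, and 0.875 with an estimated correlation). Myh7, Myl2 and Ryr2 lost their calls without Vehicle 1, Vehicle 2 or Vehicle 3 (edgeR adjusted p from 0.0613 to 0.15), Myh7 (0.0693) and Ryr2 (0.0936) also without EPO 2, and limma-voom called neither Myl2 nor Myh7 (adjusted p = 0.179 and 0.298). Of 14 chondrocyte-like genes, 8 were higher and 2 lower (adjusted over the list alone, 8 and 2; median 1.6; camera adjusted p = 7.97e-06, and 0.19 with an estimated correlation). Besides Col11a1, Acan, the cartilage proteoglycan aggrecan, rose 4.73-fold (34.8 ± 6.52 to 164 ± 16.2 CPM, adjusted p = 0.00105). The lower members, named after their values were seen, were Cytl1 (-1.43) and Hapln1 (-1.81), and Hapln1 lost its call without Vehicle 2 (adjusted p = 0.0732) or EPO 2 (0.0564). Col2a1, the main cartilage collagen, had a log2 fold change of 0.03 and did not pass. Without EPO 3 the median of the chondrocyte-like list was 0.92.

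**Figure D3:**
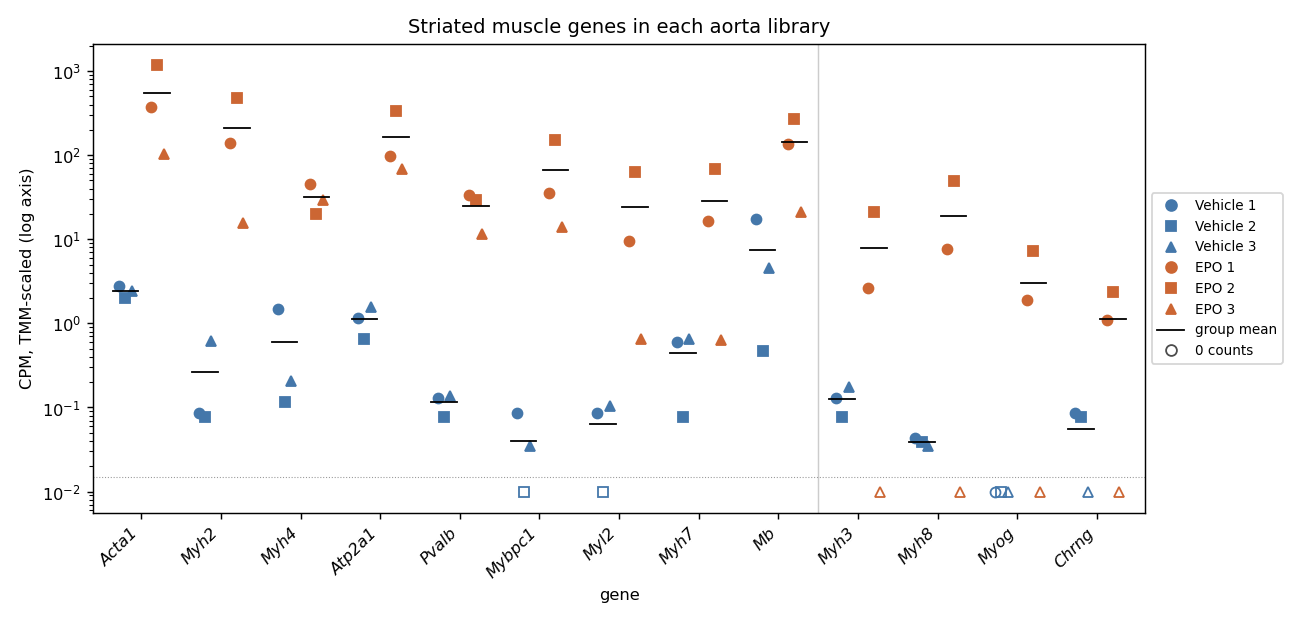
CPM of 13 striated muscle genes (horizontal axis) in each of the 6 libraries, on a log axis, with black bars at the group means and open symbols under the dotted line for libraries with 0 counts. EPO 2 lies above every Vehicle library for each gene and above EPO 1 except for Pvalb and Myh4, while EPO 3 has 0 counts of Myh3, Myh8, Myog and Chrng.

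White adipocyte genes fell. Of 15 tested, 10 were lower and 0 higher (adjusted over the list alone, 14 and 0; median log2 fold change -1.62; camera adjusted p = 4.94e-08, 0.384 with an estimated correlation and 0.0577 in fry). The adipokine Retn was 4.39-fold lower (43.3 ± 7.92 to 9.86 ± 0.882 CPM) and Plin1, a coat protein of lipid droplets, 3.29-fold lower (432 ± 191 to 131 ± 21.9 CPM), at edgeR adjusted p = 0.00105 and 0.0111. The lower members numbered 5 without Vehicle 1 or Vehicle 2, 3 without EPO 2, 6 without EPO 3, 1 without EPO 1 and EPO 2 and 5 with the replicate block, and the median was -1.06 without Vehicle 2. Of 14 brown adipocyte genes, 3 were lower and 0 higher (adjusted over the list alone, 5 and 0; median -1.04; camera adjusted p = 0.00236, and 0.526 with an estimated correlation), namely Cidea (275 ± 141 to 87.6 ± 27.9 CPM, 0.0299), Slc27a2 (0.0399) and, named after its values were seen, Dio2 (0.0474). Their number was 0 without Vehicle 1, Vehicle 2 or EPO 2, 1 without EPO 1 or EPO 3, 9 without Vehicle 3, and 7 in DESeq2 or with no filter on low counts, the median was -0.67 without Vehicle 2 and -1.64 without EPO 1 and EPO 2, and the adjusted p of the 3 genes where leaving out 1 library ended a call lay between 0.0696 and 0.148 (without EPO 1 and EPO 2, Cidea 0.116, Slc27a2 0.265 and Dio2 0.306; with library sizes alone as scaling, Dio2 0.0512). All 14 neuron and Schwann cell genes had a fold change below 0 (median -1.10; camera adjusted p = 0.00584, and 0.526 with an estimated correlation), but 1 passed, Cdh19 (4.14 ± 0.716 to 1.93 ± 0.521 CPM, 0.0314), and 0 when adjusted over the list alone. Vehicle 3 stood apart, with a median relative to the Vehicle mean of 0.56 against -0.32 and -0.51 in Vehicle 1 and 2, and the EPO libraries were at -1.18, -1.18 and -0.72. DESeq2 called 6 lower members, edgeR 7 with no filter on low counts and 6 with the replicate block. The lower members numbered 0 without Vehicle 1, Vehicle 3 or EPO 2 and 4 without Vehicle 2, and Cdh19 lost its call without any library other than EPO 3 (adjusted p from 0.0565 to 0.0956). Of 9 mesothelial genes, 2 were lower and 0 higher (adjusted over the list alone, 2 and 0; median -1.55; camera adjusted p = 0.0206, and 0.526 with an estimated correlation), Krt18 (13.8 ± 1.57 to 4.23 ± 0.519 CPM, 0.00234) and Upk1b (0.0332). The list's median was -0.52 without Vehicle 1, where its camera adjusted p was 0.121, and -0.87 in limma-voom with sample weights, where it was 0.109. Without EPO 1 the camera adjusted p was 0.0709, without EPO 1 and EPO 2 it was 0.115 (median -0.98), and with a CPM of at least 1 in 3 samples 0.0504. Its lower members numbered 4 in DESeq2 or with no filter on low counts and 1 in limma-voom, and they numbered 4 without Vehicle 3 and 1 without any 1 of the other libraries, where Upk1b lost its call (adjusted p from 0.0725 to 0.112). Of 13 adventitial fibroblast genes, 2 were higher, Col14a1 (341 ± 27.2 to 778 ± 131 CPM, 0.00434) and Serpinf1, and 4 lower, Pcolce2 (109 ± 15 to 43.6 ± 10.9 CPM, 0.00566), Clec3b, Gsn and Scara5 (adjusted over the list alone, 4 and 4; median -0.07; camera adjusted p = 0.639, and 0.817 with an estimated correlation). The median was 0.04 without Vehicle 1, 0.06 without EPO 2, -0.14 without Vehicle 2, -0.17 without Vehicle 3 and 0.155 without EPO 1 and EPO 2. DESeq2 called 4 higher members. There was 1 higher member without Vehicle 1, Vehicle 2, Vehicle 3 or EPO 3, and there were 2 lower ones without Vehicle 1. Serpinf1 lost its call without these 4 libraries (adjusted p from 0.0539 to 0.0885), Gsn without Vehicle 1 (0.0521) or EPO 2 (0.0555), and Scara5 without Vehicle 1, Vehicle 2 or EPO 3 (from 0.0839 to 0.102). Serpinf1, Clec3b, Gsn and Scara5 were named after their values were seen. Of the liver and adrenal cortex list 2 genes, Cyp11a1 and Star, were expressed enough to be tested, and neither passed in edgeR (log2 fold changes -1.08 and 0.17, adjusted p = 0.217 and 0.709).

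The lists on tissue handling had members that fell. Of 17 immediate early and stress genes, 1 was higher, Egr2, and 5 lower, Nr4a1 (165 ± 36.1 to 73.3 ± 9.81 CPM, edgeR adjusted p = 0.00621), Fosb (28.9 ± 3.88 to 15.1 ± 3.34 CPM, 0.0146), Dusp1, Atf3 and Hspa1a (adjusted over the list alone, 1 and 6; median log2 fold change -0.18; camera adjusted p = 0.125, and 0.526 with an estimated correlation). The lower members numbered 1 without Vehicle 2 and 2 without Vehicle 3 or EPO 2, and Egr2 lost its call without any library other than EPO 1 (adjusted p from 0.078 to 0.139). Fosb lost its call without Vehicle 2 (0.0572), and Dusp1, Atf3 and Hspa1a without 4 or 5 of the libraries (from 0.0538 to 0.138). The list passed camera without Vehicle 1 (adjusted p = 0.0267), though its median there was -0.09. The median was -0.10 without EPO 2, -0.30 without EPO 3 and -0.09 without EPO 1 and EPO 2. DESeq2 called 2 higher members, and limma-voom 0 higher and 3 lower. Of 16 circadian clock genes, 1 was higher, Nfil3 (13.2 and 25.5 CPM), and 4 lower, Hlf (51.7 ± 23 to 8.83 ± 1.91 CPM, adjusted p = 0.0034), Cry2 (56 ± 5.18 to 29.5 ± 2.6 CPM, 0.0037), Nr1d1 and Per2 (adjusted over the list alone, 1 and 6; median -0.82; camera adjusted p = 0.00619, and 0.308 with an estimated correlation). DESeq2 called 8 lower members and limma-voom with sample weights 11. The median was -1.28 without EPO 1 and -0.48 without EPO 2. Without EPO 1 there were 11 lower members, and Nfil3 lost its call without any library other than EPO 1 (adjusted p from 0.0706 to 0.0914), as did Per2 without Vehicle 2, Vehicle 3, EPO 2 or EPO 3 (from 0.11 to 0.147). Egr2, Dusp1, Atf3, Hspa1a, Nfil3, Nr1d1 and Per2 were named after their values were seen. The hour at which each aorta was taken is not given in the sources used here.

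Among the remaining shares of counts, ribosomal protein genes took 2.79% ± 0.264 in Vehicle and 3.66% ± 0.727 in EPO (SD, n = 3; exact permutation p = 0.2), immunoglobulin genes 0.0223% ± 0.00817 and 0.0736% ± 0.0356 (exact p = 0.1) and the 10 most counted genes 8.42% ± 1.11 and 11.7% ± 0.398 (exact p = 0.1). The tests were two-sided, 7 shares were compared in this family (those of collagen I and III and of skeletal muscle genes added after seeing the data), and after Benjamini-Hochberg adjustment each exact p of 0.1 became 0.14, so none of the shares reached 0.05, which 3 libraries against 3 cannot do.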

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

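The settings were chosen before the data were examined, except the thinned libraries, the fit without EPO 1 and EPO 2 and the removal of other-tissue genes, which were chosen after seeing the data. With 1 library left out, 1635 to 4281 genes changed, 936 to 2265 of them higher and 699 to 2016 lower, and 17 to 22 lists shifted, with fewer samples in each fit. Without EPO 1 and EPO 2, 1548 genes changed (1085 higher, 463 lower), where the lone EPO library is assumed to vary like the others; fewer samples were fitted. A fold of at least 2 left 2248 genes (1329 higher, 919 lower), fewer by its construction. An estimated correlation left 1 list called and fry 9, which tests another question. Lists lost their call at estimates from 0.034 (chondrocyte-like), near the preset 0.01, to 0.895 (oxidative phosphorylation). Collagen and elastic fibre kept its call at an estimate of -0.0315. The loss of a call is therefore no measure of how correlated the genes of a list are, and its cause was not tested further. With the replicate number as a replicate block, 2884 genes changed (1630 higher, 1254 lower) and 21 lists shifted. The labels do not say whether replicate numbers are shared between groups. The correlation of deviations was -0.0088, -0.0098 and 0.127 for equal numbers and -0.101 to 0.12 for others. With 3 libraries per group these values cannot decide whether equal numbers were paired. DESeq2 called 4962 genes and limma-voom 3481. Among the genes named in the report and followed over the settings, limma-voom lost the calls of Sv2c, Myh2, Myl2, Myh7, Csf3r, Lyz1, Iglc2, Jchain, Mzb1, Ndufa9, Slc27a2, Upk1b, Atf3, Egr2, Hspa1a, Nfil3, Per2 and Dlk1 (adjusted p from 0.0511 to 0.298). The replicate block lost those of Sv2c, Epas1, Pecam1, Adgre1, Msr1, Lyz1, Foxp3, Igkc, Iglc2, Jchain, Mzb1, Lipa, Myh7, Ryr2, Dio2, Slc27a2, Upk1b, Scara5, Atf3, Egr2, Hspa1a, Nfil3, Per2, Rian and Dlk1 (from 0.05 to 0.126). Over all genes followed and all settings, 2796 results kept their side of the threshold, 354 missed it and 33 newly passed it. For lists these were 535, 45 and 4, and the 40 alternative shares moved by less than 1 SD. A gene or list that passed in neither fit was counted as kept even where its sign changed. In the fits listed here none of the 3804 calls took the opposite sign.

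Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many changed genes: 3804, against 0 as the highest of the others. With 10 splits the share cannot go under 0.05. Each other split mixes EPO and Vehicle libraries in both of its groups, so the difference between EPO and Vehicle widens the spread within them. Their 0 calls are therefore no clean measure of what chance gives. In the other splits edgeR gave 104 to 689 genes at an unadjusted p under 0.05 and limma-voom called 0. After thinning every library to the smallest total, 3762 genes changed, and 3627 of the 3804 were still called in the same direction, so the deeper EPO libraries do not account for most calls. Epo, with 3 counts over the Vehicle group and 1 over the EPO group, was too low to be tested. Myh3, Myh8, Myog and Chrng were not tested because they had few counts in Vehicle and 0 in EPO 3, which is not a matter of depth.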

Other observations

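The genes in this part were chosen after their values were seen, as were all tests below except that of the 16 imprinted genes, whose prediction was written before.

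H19, an imprinted noncoding RNA, was at 2.22 ± 0.554 CPM in Vehicle and 210 ± 133 CPM in EPO (SD, n = 3; log2 fold change 6.55, SE 0.63, edgeR adjusted p = 0.00188), Mest at 2.97 ± 0.159 and 82.3 ± 75.5 CPM (adjusted p = 0.00514) and Hmga2, a chromatin protein of embryonic growth, at 0.202 ± 0.065 and 2.69 ± 1.3 CPM (0.00453). Plagl1 (1.39), Igf2bp2 (1.35) and Grb10 (1.52) rose as well on the log2 scale, while Igf2 had a log2 fold change of 1 and did not pass (0.225). Dlk1, which is imprinted too, was called higher in edgeR, but not without Vehicle 1, Vehicle 2, Vehicle 3 or EPO 2 (adjusted p from 0.0755 to 0.116). In limma-voom its log2 fold change was 1.89 (adjusted p = 0.0701). The imprinted gene Meg3 did not pass in edgeR, while DESeq2 called it (log2 fold change 1.08, adjusted p = 0.0144). The hypothesis that imprinted growth genes were raised as a set was tested on 16 other imprinted genes, of which 15 could be tested. Their median log2 fold change was 0.03 (p = 0.795 in camera on the edgeR fit, not a permutation). Of these genes 4 were higher (Rian, Mirg, Begain and Igf2r) and 3 lower (Slc22a3, Sgce and Snrpn). These values argue against a rise of these 15 genes as a set and leave open a rise of some of them. A subset chosen for a role in growth was not tested. Without single libraries Rian, Mirg, Sgce and Snrpn lost their calls (adjusted p from 0.0518 to 0.115).

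Arg1, arginase, was at 1.91 ± 1.24 CPM in Vehicle and 96.6 ± 53.2 CPM in EPO (edgeR adjusted p = 0.00292), Cthrc1 at 3.95 ± 2.08 and 87.5 ± 42.2 CPM, Runx2, a transcription factor of bone, at 3.54 ± 1.27 and 15 ± 1.05 CPM (0.00379), and Col10a1, a collagen of hypertrophic cartilage, at 1.19 ± 0.843 and 203 ± 161 CPM (0.00466). Sost, which encodes the bone inhibitor sclerostin, fell from 716 ± 198 to 122 ± 72.4 CPM (0.0138; 0.0504 without Vehicle 1). The developmental muscle genes Myh3, Myh8, Myog and Chrng had 710, 1713, 282 and 108 counts over the EPO group and 10, 3, 0 and 4 over the Vehicle group, with 0 counts of each in EPO 3. Th and Dbh, enzymes of noradrenaline synthesis, were at 30.4 and 62 CPM in Vehicle 3, against at most 3.91 CPM in any other library, and did not pass in edgeR (adjusted p = 0.071 and 0.0755; 0.0476 and 0.0498 without Vehicle 2, 0.0127 and 0.0141 with no filter on low counts, 0.0142 and 0.00717 with the replicate block), while DESeq2 called both (0.0389 and 0.0271).

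The summed share of counts of the skeletal muscle list was higher in each EPO library, though Casq1 did not pass and Myh3, Myh8, Myog and Chrng had 0 counts in EPO 3. Muscle of 1 composition added to every EPO library is argued against, because the log2 ratio of EPO 2 to EPO 3 ranged over 5.53 between muscle genes, from 4.95 for Myh2 to -0.58 for Myh4, and over 3.1 without the myosin heavy chains, whose counts are uncertain (3.79 for Mylpf to 0.68 for Mybpc2). Muscle of differing composition taken along at dissection may be the source and stays open: the lowest EPO share of muscle counts was 6.01 times the highest Vehicle share, and the 6 libraries hold no value that decides. An effect of EPO on striated muscle genes within the aorta stays open as well and was not tested.

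The rise of cell cycle and matrix genes could come with cells that entered with the muscle in a fixed proportion. If the summed share measured the amount of muscle, the excess of the lists per percent of muscle counts should be alike in the EPO libraries. It was 21, 9.57 and 107 in EPO 1, 2 and 3 for cell cycle, a spread of 11.2-fold. For collagen and elastic fibre it was 8.82, 2.86 and 12.9, a spread of 4.5-fold. This argues against an excess in proportion to the summed muscle counts. The log2 ratio of EPO 2 to EPO 3 differed between muscle genes, however (4.95 for Myh2, -0.58 for Myh4). The summed share may therefore not follow the amount of muscle, so cells that came with the muscle stay open. Other mixtures and an effect of EPO stay open too.

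The fall of smooth muscle genes could follow from fewer smooth muscle cells with all other cell types in their proportions, which would raise the markers of the others alike. Of 10 other cell type lists, 4 had medians below 0 in each EPO library, and for 2 of these, white adipocyte (10 of 15 genes lower) and neuron and Schwann cell (with Vehicle 3 apart from the other Vehicle libraries), every EPO library also lay below every Vehicle library, while for macrophages every EPO library lay above every Vehicle library, which argues against it. Endothelial cell, adventitial fibroblast, brown adipocyte, mesothelial, neutrophil, T and NK cell and B and plasma cell lists overlapped with Vehicle and do not count either way. The argument thus rests on fat, nerve and macrophage markers. The choice among the scalings tried is argued against too, since the list's median was -1.49 or lower in each. These scalings differ little, with TMM factors from 0.932 to 1.04, and a scaling of another kind was not tested. A change within smooth muscle cells and a change in several cell types at once stay open.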
